A study of Homo sapiens with 6 samples.

How the data were processed

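RNA from the human multiple myeloma cell line MM.1S was sequenced in 6 libraries, 3 from wild-type (WT) cells and 3 from a clone in which CD38 had been knocked out with CRISPR/Cas9 (CD38 KO). Per the labels' protocols, both lines carried GFP and a click beetle luciferase, live cells were sorted on CD38 surface staining (positive cells from the WT line, negative cells from the clone), and biological replicates were prepared from the sorted populations. Libraries were made from 10 ng of total RNA with an integrity number above 8.0, using a SMARTer low-input kit, per the labels' protocols. The values used here are raw read counts per gene, as deposited by the authors in 1 table with 1 column per library. The submitters' processing notes name STAR 2.7.9a, Partek and DESeq2 without saying which step each served. The genome build, the gene annotation, the counting program and the strand setting are not given in the sources used here, so counts of overlapping, antisense or near-identical genes are uncertain.

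The table held 60871 lines. A set of 200 lines repeated an Ensembl identifier with the same counts, so each identifier was kept once, which left 60671 genes. Symbols and biotypes were those of the table. Chromosomes and gene order came from GENCODE release 29 through the Ensembl identifier, and that release may not be the annotation the authors counted with; 98.5% of the tested genes had a chromosome. Total counts ranged from 61515519 to 72335496 per library. At this depth a count of 0 allows up to 3 counts in a library, on average 0.0438 CPM in WT and 0.0486 CPM in CD38 KO, where CPM is the count scaled to library size with TMM factors. Such floors and the 95% counting intervals cover counting error only, since reads without molecular identifiers are not independent molecules. Every pair of libraries differed by more than sampling noise, with a chi-square per degree of freedom of at least 5.96.

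CD38 KO was compared with WT in R 4.3.3 by the quasi-likelihood test of edgeR 4.0.16, with TMM factors, filterByExpr, robust dispersion estimates and no covariate. The p-values were adjusted by the Benjamini-Hochberg method. Genes with an adjusted p under 0.05 were called changed, and a 2-fold change needed in addition a log2 fold change of at least 1 in size. The 31 gene lists (960 entries) and every chromosome were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at a preset inter-gene correlation of 0.01 and again with an estimated one, with Benjamini-Hochberg adjustment over the lists or chromosomes. camera asks whether the genes of a list rank higher or lower than other genes. fry, run as an alternative, tests whether the genes of a list move on balance one way and does not compare them with other genes. Only 1 list entry matched no symbol of the table, and 45 symbols stood on more than 1 list.

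The lists, the tests, the alternatives and the rule for naming genes were fixed before the data were examined. The rule takes CD38, then the 12 protein-coding genes higher and the 12 lower with the largest log2 fold changes among those with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups. It adds up to 4 members of every list with the smallest adjusted p, the tested neighbours of CD38, and the clinical targets TNFRSF17, GPRC5D, SLAMF7, FCRL5, SDC1, CRBN, IKZF1 and IKZF3. Some genes this rule takes are not reported here. Any other gene named was chosen after its values were seen.

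The alternatives were RLE, upper-quartile and no composition factors, no filter on low counts, a filter at 1 CPM in 3 libraries, DESeq2 1.42.0 (genes only), limma-voom, the replicate number as a block, each library left out in turn, a test against a 2-fold change, protein-coding genes only, an estimated correlation, fry, and lists without CD38 and genes shared between lists. Fits without chromosomes 12, 13 and 15 and without mitochondrially encoded genes were chosen after seeing the data. Chromosome arms were not tested, since the annotation used here gives none.

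The procedure was tested on simulated counts with the means, library sizes and groups of this comparison. Among 19197 simulated genes it recovered 67.5% of the genes changed 1.5-fold, 89.1% of those changed 2-fold and 100% of those changed 4-fold, and 7.74% of its 181 calls were false. The simulation changed far fewer genes than the data, where 8934 were called, and only genes at 1 CPM or more in WT. These shares hold for that setting and are not the recovery or false calls of the real comparison. In the step on lists, which ran on 19252 genes, 1% of random lists passed an unadjusted p of 0.05 with the preset correlation and 0% with the estimated one, while a shifted list had camera p = 1.65e-55 with the preset and p = 5.75e-05 with the estimated correlation. The simulated genes varied independently of each other, whereas the estimated correlation of the real lists reached 0.817, for ribosomal proteins. This step therefore cannot show whether the preset correlation is enough for lists whose genes vary together. With 3 libraries against 3, an exact permutation test cannot give a p below 0.1.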

Results

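The transcriptomes of MM.1S cells, a human multiple myeloma line, were compared between wild-type cells and a CRISPR/Cas9 knockout clone of CD38, the surface glycoprotein with NAD-hydrolysing activity that anti-CD38 antibodies bind on myeloma cells. According to the labels, the comparison was made to describe the knockout phenotype. Each group had 3 libraries. The WT libraries held 72335496, 63606445 and 64322374 counts and the CD38 KO libraries 65709440, 61515519 and 63706270. Log2 CPM correlated between libraries of the same group with Pearson's r of 0.986 to 0.991 and between groups with 0.961 to 0.964, across genes, which are not independent replicates. The first principal component separated the groups and held 68.2% of the variance.

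CD38 (ENSG00000004468; chromosome 4, 15778275 to 15853230 in GENCODE 29, build GRCh38) was examined first as a check of the labels. The WT libraries held 3148, 2678 and 2545 CD38 counts and the CD38 KO libraries 51, 80 and 48. Its level was 40.6 ± 1.90 CPM (SD, n = 3) in WT and 0.972 ± 0.322 CPM (SD, n = 3) in CD38 KO, 2.40% of the WT level, with a log2 fold change of -5.39 ± 0.134 (SE; edgeR adjusted p = 3.06e-16). The cells had been sorted for CD38 protein, for its presence in WT and its absence in the clone, so the sort selected in the same direction as the genotype.

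Against WT, the CD38 KO clone had almost no transcripts of several genes that WT cells expressed, and expressed others that were near 0 in WT. The lysosomal protease CTSL was at 30.8 ± 0.645 CPM (SD, n = 3) in WT with 0 counts in every CD38 KO library, at least 634-fold lower against a floor of 3 counts per library. DDIT4L, an inhibitor of mTOR signalling, was at 17.98 ± 0.920 CPM (SD, n = 3) in WT, also with 0 counts in every CD38 KO library, at least 370.0-fold lower. LY6E, a GPI-anchored surface protein induced by interferon, had 7 counts over the 3 WT libraries and stood at 40.5 ± 2.27 CPM (SD, n = 3) in CD38 KO, a count ratio of 1190 with a 95% counting interval of 577 to 2960. The anti-inflammatory cytokine IL10 rose from 0.274 ± 0.187 to 23.6 ± 0.660 CPM and SOCS3, the feedback inhibitor of STAT3 signalling, from 1.71 ± 0.164 to 61.9 ± 2.14 CPM (SD, n = 3). The log2 fold change of LY6E was 10.14 and without WT replicate 1 12.05, and that of IL10 was 6.45 and without WT replicate 2 7.08.

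In all, 8934 of 20120 tested genes (44.4%) were changed at an edgeR adjusted p under 0.05, 4592 higher and 4342 lower in CD38 KO. With library size alone as the scaling, 3632 genes were higher and 5570 lower. The median size of the log2 fold change among the changed genes was 0.534, and 2266 genes were changed at least 2-fold, 1208 higher and 1058 lower. This count was 1323 with a filter at 1 CPM, 690 higher and 633 lower, and 1061 when edgeR tested against a 2-fold change. The CPM of the groups did not overlap for 52.5% of the tested genes, where chance gives 10%. The common biological coefficient of variation was 0.0807. The knockout libraries come from 1 clone, so the p-values measure the difference between that clone and this WT population against the spread of their replicates.

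Besides LY6E, IL10 and SOCS3, the genes with the largest rises under the naming rule included the class I myosin MYO1F, the helicase DHX40, the netrin receptor DCC, the protocadherin PCDH12, the collagen chaperone SERPINH1, the UDP receptor P2RY6, the bile salt-stimulated lipase CEL and SPNS3, a relative of the sphingolipid transporter SPNS2. MYO1F went from 0.281 ± 0.0885 to 20.04 ± 1.68 CPM and SPNS3 from 1.18 ± 0.0357 to 18.95 ± 1.29 CPM (SD, n = 3). Among the largest falls, the zinc finger repressor ZNF536 was at 91.6 ± 3.62 CPM (SD, n = 3) in WT with 5 counts over the CD38 KO libraries, a count ratio of 3402 (95% counting interval 1457 to 10480). The DNA end-joining factor PAXX had 2 counts in CD38 KO (count ratio 1200, 331.8 to 9913), the microsomal glutathione transferase MGST1 had 6 (889.9, 408.6 to 2426) and SPIN3, one of several similar spindlin genes between which reads may be shared, had 3 (624.4, 213.4 to 3030). AHNAK, the lymphocyte receptor SLAMF6, the squalene epoxidase SQLE, the growth factor binding protein IGFBP3 and ZNF655 had log2 fold changes of -5.84, -4.95, -4.51, -4.51 and -4.48. SLAMF6 had 2, 56 and 6 counts in the CD38 KO libraries, and its log2 fold change was -7.37 without CD38 KO replicate 2. Among the genes near 0 in CD38 KO, the 2 counts of PAXX and the 3 of SPIN3 all came from CD38 KO replicate 2. The log2 fold change of MGST1 went from -9.72 to -10.62 without CD38 KO replicate 1 and that of ZNF536 from -11.63 to -12.30 without CD38 KO replicate 3. IGFBP3 went from 236.4 ± 2.96 to 10.4 ± 0.322 CPM (SD, n = 3).

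**Figure D1:**
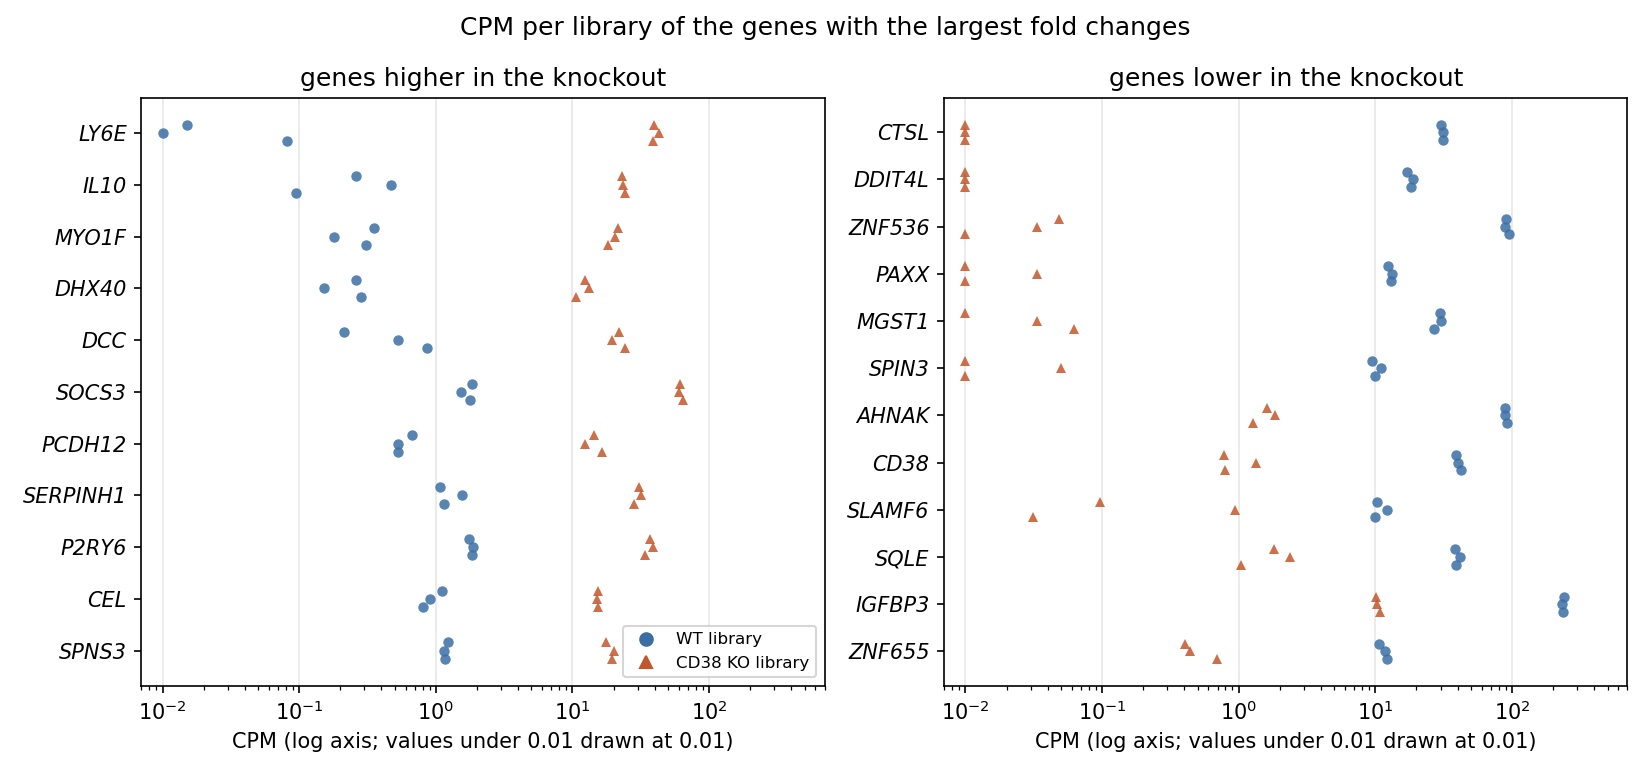
CPM (log axis) of protein-coding genes with the largest rises and falls in CD38 KO under the naming rule, 1 point per library, with WT as circles and CD38 KO as triangles. Values under 0.01 CPM are drawn at 0.01, where CTSL and DDIT4L lie in CD38 KO with 0 counts.

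Among the targets of myeloma therapy, TNFRSF17 (BCMA) rose and SLAMF7 fell. TNFRSF17 went from 227.4 ± 8.50 to 356.3 ± 13.4 CPM (SD, n = 3; log2 fold change 0.65, edgeR adjusted p = 4.23e-11), and SLAMF7 from 733.2 ± 2.67 to 565.8 ± 7.02 CPM (SD, n = 3; log2 fold change -0.37, edgeR adjusted p = 1.18e-08). FCRL5 rose from 0.391 ± 0.153 to 2.89 ± 0.438 CPM (SD, n = 3). IKZF1, a lymphoid transcription factor degraded under immunomodulatory drugs, went from 87.05 ± 4.77 to 47.4 ± 0.776 CPM (SD, n = 3), and its relative IKZF3 rose by a log2 fold change of 0.26. GPRC5D, SDC1 (CD138) and CRBN were not past the threshold, with log2 fold changes of 0.0931, 0.0362 and -0.00493 and edgeR adjusted p of 0.220, 0.488 and 0.955.

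By camera with the preset correlation, 10 of the 31 gene lists were past the threshold, 7 higher and 3 lower in CD38 KO. With an estimated correlation camera gave 0, with 4 at an unadjusted p under 0.05, and fry gave 23. The mitochondrially encoded genes had the largest median: all 15 rose, with a median log2 fold change of 1.31 (camera adjusted p = 4.09e-11). For this list the adjusted p = 0.348 with an estimated correlation, within a camera range of 5.53e-20 to 0.348 over the alternatives. MT-CO2 went from 1713 ± 44.0 to 5818 ± 100.4 CPM and MT-RNR2 from 9848 ± 215.9 to 29840 ± 565.9 CPM (SD, n = 3), and MT-ATP6 and MT-CYB rose by log2 fold changes of 1.31 and 1.72. The mitochondrial share of all counts was 2.63%, 2.71% and 2.69% in the WT libraries and 7.30%, 6.83% and 7.16% in the CD38 KO libraries (two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give). Reads from nuclear copies of mitochondrial genes may be counted with either. Of 37 nuclear genes of oxidative phosphorylation, 14 rose and 4 fell, 15 and 4 adjusted over the list alone (camera adjusted p = 0.0991). UQCRC1, COX5A and UQCRC2 rose by log2 fold changes of 0.44, 0.49 and 0.38, and SDHC was lower, at -0.45. That list was past the threshold without CD38 KO replicate 1 (camera adjusted p = 0.0171) and with limma-voom (0.0318), in a range of 0.0171 to 0.780 over the alternatives.

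Cell cycle genes moved in opposite directions. Of 44 tested, 27 rose and 16 fell, with a median log2 fold change of 0.85 (camera adjusted p = 0.00488). The adjusted p = 0.386 with an estimated correlation, within a camera range of 2.41e-05 to 0.386 (fry adjusted p = 1.71e-05). The mitotic genes CCNB1, CDC20, PLK1 and UBE2C rose by log2 fold changes of 1.91, 1.91, 1.78 and 1.83, with CCNB1 going from 68.1 ± 1.86 to 255.5 ± 5.48 CPM (SD, n = 3). The members that fell, named here after their values were seen, included the replicative helicase subunits MCM5 (-0.84) and MCM6 (-0.83), the clamp PCNA (-0.42) and E2F1 (-0.56), which act in G1 and S phase. Of 21 histone genes, 9 rose, among them H2AX, H2AZ1, H2AC6 and H2BC8, and 2 fell (median 0.54, camera adjusted p = 0.0347). For histone genes the adjusted p = 0.590 with an estimated correlation. Their call was also lost without WT replicate 1 (camera adjusted p = 0.0752), without CD38 KO replicate 2 (0.0510) and with a filter at 1 CPM (0.173, where the median was 0.17), in a range of 0.00147 to 0.590 over the alternatives. Many histone genes are near-identical copies between which reads may be split, and H2BC8 had only 23, 36 and 16 counts in the WT libraries.

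Most of the sterol and fatty acid synthesis genes rose. Of 29 tested, 22 rose, 5 were not past the threshold and 2 fell, SQLE and the sterol exporter ABCG1, the latter named after its values were seen (median log2 fold change 0.49, camera adjusted p = 1.29e-05). The adjusted p = 0.348 with an estimated correlation, within a camera range of 1e-08 to 0.348 (fry adjusted p = 7.35e-05). The desaturase SCD went from 634.7 ± 27.7 to 1402 ± 23.5 CPM (SD, n = 3), and INSIG1 and the transcription factor SREBF1 rose by log2 fold changes of 0.81 and 0.97. SQLE, which converts squalene on the way to lanosterol, went from 39.6 ± 1.95 to 1.74 ± 0.672 CPM (SD, n = 3; edgeR adjusted p = 1.46e-08).

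Of 25 unfolded protein response genes, 17 rose and 6 fell (median 0.29, camera adjusted p = 0.0199). The adjusted p = 0.348 with an estimated correlation, within a camera range of 0.000934 to 0.348 (fry adjusted p = 2.46e-05). XBP1, ERN1 (the sensor IRE1) and EDEM1 rose by log2 fold changes of 0.75, 0.72 and 0.55, while the chaperone HSP90B1 went from 2167 ± 33.7 to 1423 ± 24.8 CPM (SD, n = 3). Of 24 integrated stress response genes, 16 rose and 4 fell (median 0.28, camera adjusted p = 0.00488). The adjusted p = 0.444 with an estimated correlation, within a camera range of 0.000337 to 0.444 (fry adjusted p = 0.000190). DDIT4 went from 20.02 ± 1.02 to 82.2 ± 5.62 CPM (SD, n = 3), SLC7A1 and TRIB3 rose, and CHAC1, a glutathione-degrading target of ATF4, fell from 84.9 ± 2.97 to 42.5 ± 1.68 CPM (SD, n = 3).

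Of 21 genes of MHC class I presentation, 14 rose and 2 fell (median 0.23, camera adjusted p = 0.0113). The adjusted p = 0.444 with an estimated correlation, within a camera range of 0.00181 to 0.444 (fry adjusted p = 0.000838), and the median was 0.14 with library size alone. HLA-E, PSMB8 and TAPBPL rose by log2 fold changes of 0.51, 0.53 and 0.49, whereas B2M, the light chain of class I molecules, went from 2623 ± 169.4 to 1524 ± 41.4 CPM (SD, n = 3). HLA genes are alike in sequence, and their reads may be shared. The counts of higher and lower genes adjusted over the list alone were 15 and 2 for this list, and the same as over all genes for the other 9 lists past the threshold.

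Among earlier B-lineage markers, the MAF program and MYC targets, more genes fell than rose in CD38 KO. Of 21 earlier B-lineage markers, 10 fell and 3 rose (median -0.37, camera adjusted p = 0.0331), and the adjusted p = 0.348 with an estimated correlation. CD37 went from 10.04 ± 0.663 to 0.676 ± 0.114 CPM, the complement receptor CR2 from 51.1 ± 2.97 to 19.4 ± 0.392 CPM and the transcription factor SPI1 (PU.1) from 43.4 ± 1.15 to 18.4 ± 1.23 CPM (SD, n = 3), while PTPN6 rose. This call was also lost with library size alone (camera adjusted p = 0.0608), a filter at 1 CPM (0.0520) and lists without CD38 and shared genes (0.0623), in a camera range of 0.00984 to 0.348 (fry adjusted p = 1.71e-05), and without CD38 KO replicate 2 the median was -0.65. Of 18 genes of the MAF program, which MAF drives in myelomas with a MAF translocation, 11 fell and 4 rose (median -0.39, camera adjusted p = 0.0255), and the adjusted p = 0.350 with an estimated correlation. AHNAK went from 89.9 ± 2.22 to 1.58 ± 0.293 CPM (SD, n = 3), and NUAK1, TLR4 and RND3 had log2 fold changes of -1.64, -1.55 and -1.75. Without the genes of chromosomes 12, 13 and 15, a fit chosen after seeing the data, the MAF program had a median of -0.19 and a camera adjusted p of 0.261, in a camera range of 0.00198 to 0.350 (fry adjusted p = 2.46e-05).

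Of 34 MYC target and ribosome biogenesis genes, 17 fell and 5 rose (median -0.12, camera adjusted p = 0.0467), and the adjusted p = 0.454 with an estimated correlation. UTP20, ODC1 and NOP56 had log2 fold changes of -1.51, -0.52 and -0.39, and LDHA rose, at 0.52. This call was also lost without WT replicate 1 (camera adjusted p = 0.0752), WT replicate 3 (0.0827), CD38 KO replicate 1 (0.0692) or CD38 KO replicate 3 (0.128), with a filter at 1 CPM (0.0945) and without chromosomes 12, 13 and 15 (0.0569), in a camera range of 0.0183 to 0.454 (fry adjusted p = 0.00178), and with library size alone the median was -0.20.

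**Figure D2:**
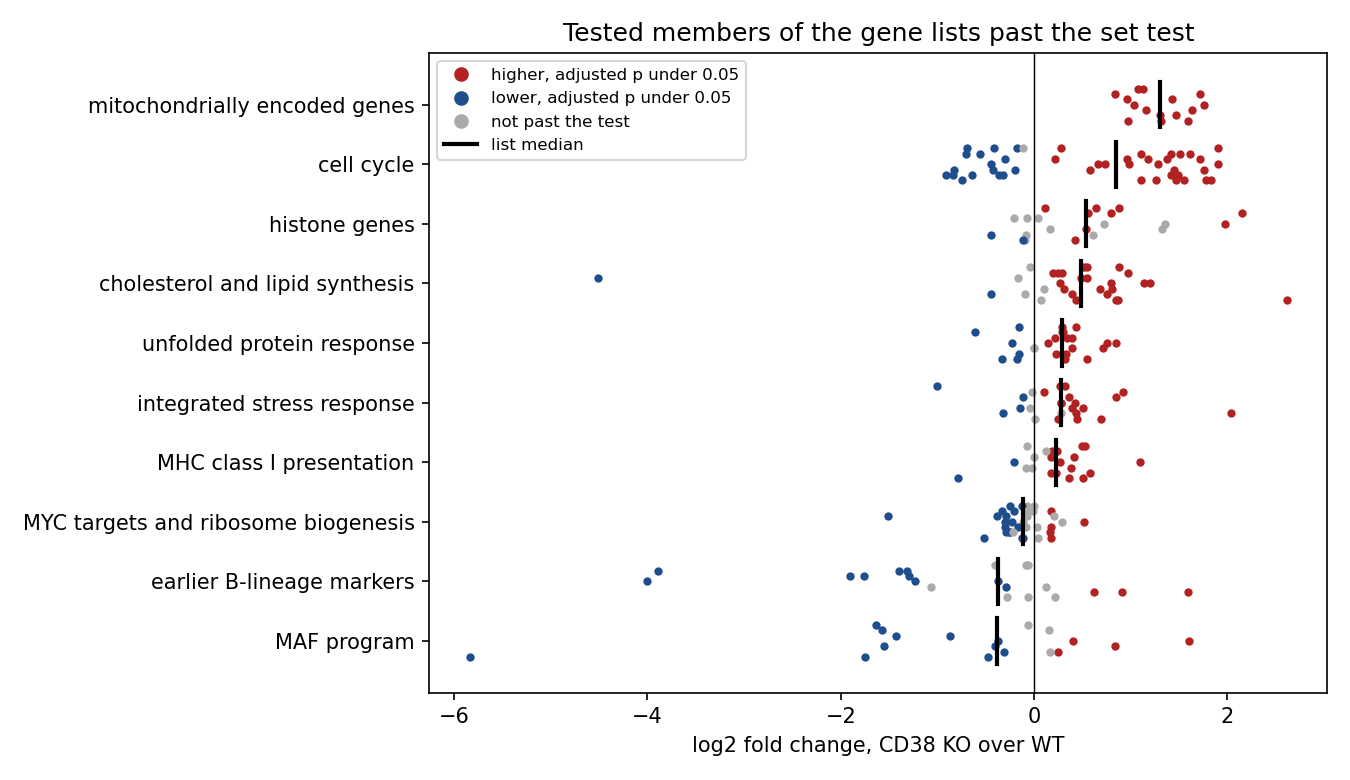
Log2 fold change in CD38 KO over WT of each tested member of the 10 gene lists past the set test with the preset correlation, 1 point per gene, with the list median as a bar. Red and blue points passed an adjusted p of 0.05, and the medians run from -0.39 for the MAF program to 1.31 for the mitochondrially encoded genes.

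Genes of NAD metabolism, calcium signalling and plasma cell identity changed in both directions, and these lists were not past the threshold by camera. Of 36 genes of NAD and adenosine metabolism, 12 rose and 8 fell, 14 and 8 adjusted over the list alone (camera adjusted p = 0.275, fry adjusted p = 0.0349). PARP9 and the adenosine deaminase ADA rose by log2 fold changes of 2.40 and 0.68, and PARP1 was lower, at -0.52. Of 35 calcium signalling genes, 12 rose and 15 fell, 13 and 15 adjusted over the list alone (camera adjusted p = 0.428, fry adjusted p = 0.0101). S100A10 and S100A6 had log2 fold changes of -3.54 and -2.59, and the calcium release channel ITPR1 rose from 17.4 ± 1.78 to 77.4 ± 8.29 CPM (SD, n = 3). Of 26 plasma cell identity genes, 14 rose and 6 fell, 15 and 6 adjusted over the list alone (camera adjusted p = 0.104). TENT5C and the joining chain JCHAIN rose by log2 fold changes of 1.33 and 1.05, and SEL1L3 was lower, at -0.96. The plasma cell list was past the threshold with no filter on low counts (camera adjusted p = 0.0384) and with limma-voom (0.0318), in a camera range of 0.0318 to 0.386 over the alternatives (fry adjusted p = 0.000190).

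Of 13 tested neighbours of CD38 on chromosome 4, 7 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.111). LAP3, NCAPG, LCORL and TAPT1 rose by log2 fold changes of 0.85, 0.71, 0.43 and 0.35. The call of FAM200B (edgeR adjusted p = 0.0486) was lost in 13 of 16 alternatives, among them DESeq2 (adjusted p = 0.093), limma-voom (0.0592) and library size alone (0.0867). It was lost without WT replicate 1 (edgeR adjusted p = 0.114), WT replicate 2 (0.0738), WT replicate 3 (0.127), CD38 KO replicate 1 (0.241) or CD38 KO replicate 3 (0.0576), in a range of 0.0232 to 0.241. That of DCAF16 was lost without WT replicate 1 (edgeR adjusted p = 0.109), WT replicate 2 (0.0527), CD38 KO replicate 1 (0.0649) or CD38 KO replicate 3 (0.0780) and with library size alone (0.156), in a range of 0.00666 to 0.156.

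Adhesion receptors and cytokines changed in both directions. Of 35 adhesion and homing genes, 16 rose and 10 fell, the same adjusted over the list alone (camera adjusted p = 0.268). PECAM1 (CD31), a ligand of CD38, went from 30.7 ± 0.932 to 128.2 ± 3.29 CPM and ICAM1 from 49.95 ± 2.46 to 152.4 ± 1.80 CPM (SD, n = 3), while the integrin ITGA8 was lower, at a log2 fold change of -1.26. Of 18 bone disease and cytokine genes, 9 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.169). The chemokine CCL4 went from 156.9 ± 4.10 to 410.3 ± 20.4 CPM and CCL5 from 45.6 ± 1.58 to 3.96 ± 0.199 CPM (SD, n = 3), and GFI1 and SEMA4D rose by log2 fold changes of 1.47 and 0.62. Of 23 mesenchymal and invasion genes, 6 rose and 9 fell, the same adjusted over the list alone (camera adjusted p = 0.428). ANXA2, CD109, CDH2 (N-cadherin) and VIM (vimentin) had log2 fold changes of -1.22, -4.22, -1.08 and -0.70. Of 30 complement regulators and immune ligands, 8 rose and 12 fell, 9 and 12 adjusted over the list alone (camera adjusted p = 0.507). The T cell ligand CD70 went from 26.9 ± 0.820 to 110.1 ± 3.91 CPM and the complement regulator CD55 from 45.1 ± 2.19 to 11.8 ± 0.686 CPM (SD, n = 3), and SIRPA and CD86 fell.

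Signalling and immune response genes were divided as well. Of 37 growth factor receptor and signalling genes, 14 rose and 12 fell, the same adjusted over the list alone (camera adjusted p = 0.808). STAT3 went from 155.6 ± 3.02 to 343.7 ± 1.93 CPM (SD, n = 3), whereas the kinase PIM1 and the cytokine receptor chain IL2RG had log2 fold changes of -1.30 and -1.27. Of 28 NF-kB pathway genes, 8 rose and 10 fell, the same adjusted over the list alone (camera adjusted p = 0.761), with BCL3 at 1.76 and PLEK at -1.43. Of 44 interferon response genes, 14 rose and 20 fell, 15 and 20 adjusted over the list alone (median -0.33, camera adjusted p = 0.380). ISG20 was among those that rose, by a log2 fold change of 1.18. Of 18 genes of MHC class II presentation, 10 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.527). The regulator CIITA, CTSS and HLA-DOB were lower, with log2 fold changes of -1.29, -0.76 and -1.52, and HLA-DQB1 rose.

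Of 28 apoptosis regulators, 12 rose and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.275), with BIRC5 and MCL1 at log2 fold changes of 1.45 and 0.75 and BCL2 and FAS at -0.70 and -0.75. Of 30 p53 targets, 7 rose and 15 fell, 8 and 15 adjusted over the list alone (median -0.14, camera adjusted p = 0.380). CCNG1, TP53INP1 and GDF15 were among those that rose, and FAS among those that fell. Of 36 glycolysis and hypoxia genes, 16 rose and 14 fell, 16 and 15 adjusted over the list alone (camera adjusted p = 0.745), with TPI1 at 0.58 and MXI1 and HK1 at -0.73 and -0.74. Of 29 immediate early and heat shock genes, 12 rose and 7 fell, the same adjusted over the list alone (camera adjusted p = 0.428), and JUNB, ZFP36, HSPB1 and EGR1 rose by 0.95, 0.78, 1.60 and 0.99 on the log2 scale. Of 42 ribosomal protein genes, 5 rose and 10 fell, 4 and 9 adjusted over the list alone (camera adjusted p = 0.380), with RPS4X at 0.52 and RPS6, RPS16 and RPL19 at -0.32, -0.36 and -0.20. The mean log2 fold change was above 0 beside a median and a test direction below 0 for the NF-kB list (mean 0.0457, median -0.0334) and for the complement and immune ligand list (mean 0.00819, median -0.0884).

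Markers of other cell types were mostly under the count filter. Of 24 T and NK cell markers 9 were tested, with 2 higher and 1 lower, the same adjusted over the list alone (camera adjusted p = 0.380). CD3E went from 0.979 ± 0.0760 to 4.83 ± 0.359 CPM and KLRF1 from 1.02 ± 0.0823 to 2.80 ± 0.347 CPM (SD, n = 3). The lower call, of NCAM1, was lost without WT replicate 1 (edgeR adjusted p = 0.0502) and without CD38 KO replicate 3 (0.0603), in a range of 0.000229 to 0.0603, and GNLY was called without CD38 KO replicate 3 (edgeR adjusted p = 0.0245), in a range of 0.0245 to 0.252. Of 24 myeloid markers 5 were tested, with FCER1G higher and ITGAM lower, the same adjusted over the list alone (camera adjusted p = 0.867). Of 27 stromal, endothelial and red cell markers 10 were tested, with PECAM1, HBB and PDGFRB higher and ACTA2 lower, the same adjusted over the list alone (camera adjusted p = 0.785). For this list camera's direction was upward beside a median of -0.52 and a mean of -0.18. The ACTA2 call was lost without WT replicate 1 (edgeR adjusted p = 0.0658), in a range of 0.00596 to 0.0658.

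The changes were also laid along the chromosomes, since a clone can differ from its parental population in chromosome content. Chromosome 13 was higher as a whole: of 392 tested genes 179 rose and 20 fell, with a median log2 fold change of 0.39 (camera adjusted p = 1.25e-07, and adjusted p = 0.0175 with an estimated correlation, the highest of its alternatives). The mitochondrial chromosome was higher (camera adjusted p = 4.50e-09, and adjusted p = 0.239 with an estimated correlation, in a range of 3.88e-15 to 0.239). Chromosome 12 passed only with the estimated correlation, with 206 genes higher and 338 lower and a median of -0.11 (camera adjusted p = 0.213, and adjusted p = 0.0451 with an estimated correlation, in a range of 0.0451 to 0.405). No other chromosome passed the threshold under either correlation. Windows of 25 consecutive protein-coding genes at 5 CPM or more were laid out after the chromosome result was seen. The last window of a chromosome also took the genes left over and held up to 49. Of 370 windows, 29 lay in runs of 3 or more whose median was beyond 0.25 in the same direction.

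These windows formed 5 segments, given in GENCODE 29 positions. Genes between 0.28 and 14.5 Mb of chromosome 12 were higher (median log2 fold change 0.39, 75 genes) and those between 39.8 and 110 Mb lower (-0.43, 275 genes). Genes from 19.6 to 114 Mb of chromosome 13 were higher (0.50, 164 genes). On chromosome 15, genes from 22.8 to 58.9 Mb were lower (-0.58, 125 genes) and those from 68.8 to 102 Mb higher (0.46, 117 genes). In each segment 82.7% to 89.0% of the window genes shared its direction. Several genes named above as list members lie on these chromosomes. Those that fell included HSP90B1, UTP20 and NUAK1 on chromosome 12 and B2M and CHAC1 on chromosome 15. Those that rose included PTPN6, TAPBPL and TPI1 on chromosome 12, SLC7A1 on chromosome 13 and ISG20 and COX5A on chromosome 15. Whether their changes belong to a regional shift or to their lists was not tested.

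**Figure D3:**
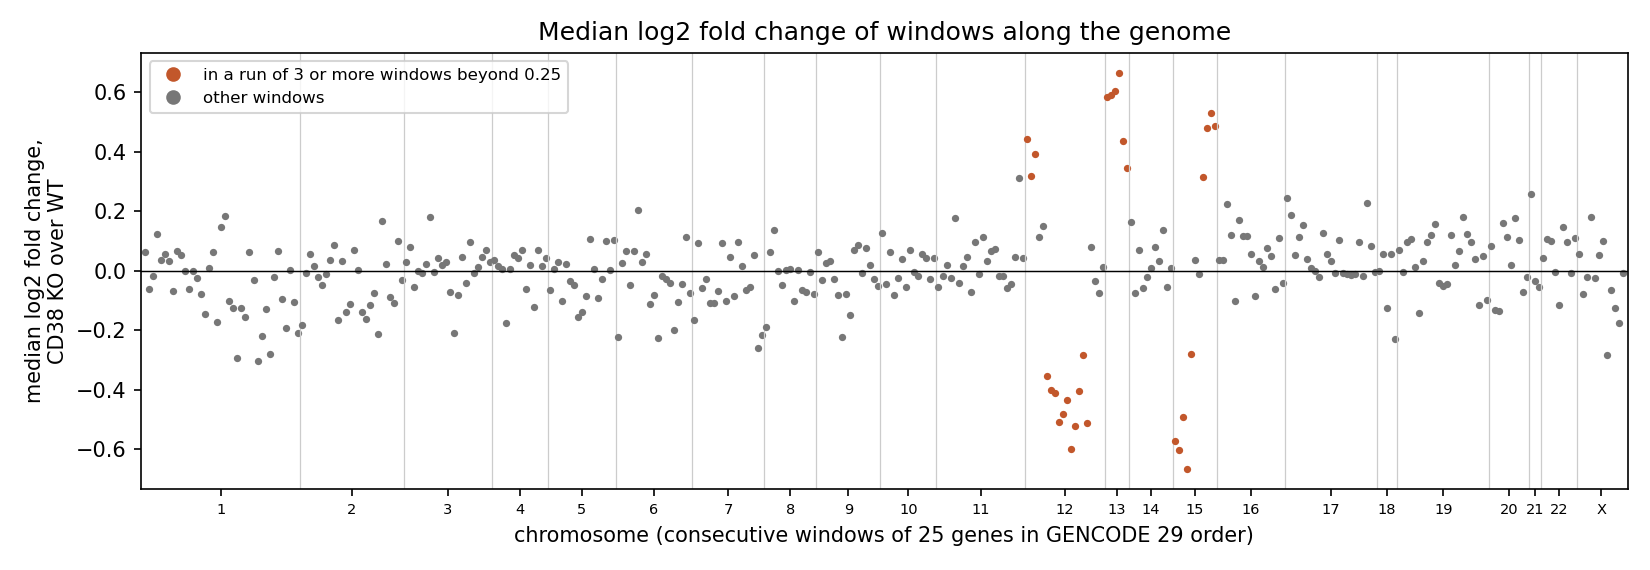
Median log2 fold change in CD38 KO over WT of 370 windows of 25 consecutive protein-coding genes at 5 CPM or more, 1 point per window, laid along the chromosomes. The last window of a chromosome held up to 49 genes. The 29 coloured windows, in runs of 3 or more beyond 0.25, lie on chromosomes 12, 13 and 15.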

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

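The fits without chromosomes 12, 13 and 15 and without mitochondrially encoded genes were chosen after seeing the data. Changed genes numbered 7767 (without WT replicate 3) to 9202 (library size alone) over the alternatives on all biotypes, 8583 with DESeq2, and every gene called both there and in the report kept its direction. With protein-coding genes only, 7637 were changed. Leaving out 1 library gave 7767 to 8761 changed genes and 2196 to 2364 changed at least 2-fold. A filter at 1 CPM left 13861 genes to test, and with these fewer genes 1323 were changed at least 2-fold, 690 higher and 633 lower. Tested against a 2-fold change, a stricter question by construction, 1061 genes passed. With an estimated correlation camera gave 0 lists past the threshold and 4 at an unadjusted p under 0.05; fry, which asks another question, gave 23, and the other alternatives 7 to 12. Without chromosomes 12, 13 and 15 there were 7793 changed genes and 8 lists, and without mitochondrially encoded genes 8907 and 9. The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated by 0.106, 0.0438 and -0.0302, and not every library correlated best with its own number. With the replicate block, 8918 genes, 2216 at 2-fold, 8 lists and 2 chromosomes passed, the MAF program (camera adjusted p = 0.0656) and MYC targets (0.0694) not among them. Chromosome 22 passed with no filter on low counts (camera adjusted p = 0.0330, in a range of 0.0330 to 0.436).

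Of the 142 named genes called, 0 changed sign, and 4 lost their call in some alternative. The sign turned for 5 genes that were not called, and the cause was not tested. With library size alone CPEB2 was at -0.0217 and SDC1 at -0.0470, and with the filter at 1 CPM CRBN was at 0.00223. With 1 library left out, CSF3R ranged from -1.118 to 0.374, CPEB2 from -0.0402 to 0.142, CC2D2A from -0.516 to 0.0833, SDC1 from -0.00443 to 0.0644 and CRBN from -0.0171 to 0.0169. Depth limits mainly the genes near the floor of 3 counts per library.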

Other observations

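The tests on iron and redox genes, GC content, gene dosage, runs of windows, depth and cell line identity were chosen only after the pattern or part of its values had been seen, while those on neighbouring genes, cell cycle phases, PU.1 and STAT3 were written before their own values were seen.

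Several iron storage and antioxidant genes fell in CD38 KO. FTL, the ferritin light chain, went from 5575 ± 122.2 to 792.8 ± 27.8 CPM (SD, n = 3; edgeR log2 fold change -2.81, adjusted p = 2.89e-22), and its processed pseudogenes may share its reads. On a list of 24 iron and redox genes written after FTL was seen and without it, 13 of 23 tested genes fell and 5 rose (median -0.21, camera adjusted p = 0.0254, adjusted p = 0.165 with an estimated correlation). PRDX1 fell from 170.5 ± 8.48 to 80.1 ± 5.58 CPM and the iron exporter SLC40A1 from 25.8 ± 1.43 to 9.80 ± 0.159 CPM (SD, n = 3). TXNRD1, NQO1, HMOX1, GCLM and GCLC, known targets of the transcription factor NRF2, had log2 fold changes of -0.79, -1.38, -0.85, -0.50 and -0.59. The transferrin receptor TFRC and IREB2 rose by 0.38 and 0.65 on the log2 scale.

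A first pattern was the shift of 5 contiguous segments on chromosomes 12, 13 and 15. A trend with GC content and transcript length is argued against for chromosome 13, whose genes had a median of 0.396 after a loess correction on both and 0.394 before. After the correction, all tested genes of the 5 segments kept their direction, with medians of 0.36, -0.36, 0.40, -0.50 and 0.36. The window genes alone had 0.39, -0.43, 0.50, -0.58 and 0.46 before it. These are different sets of genes, so the part of each shift that such a trend may hold was not measured. Chance runs are argued against as well, since the most windows in such runs over 1000 shuffled gene orders was 0, against 29. Gene dosage of contiguous segments is a candidate explanation, as tested genes left out of the windows, non-coding or low, had a median of the same sign in 5 of the 5 segments (0.35, -0.26, 0.16, -0.39 and 0.28). The window medians correspond to ratios of 1.31, 0.741, 1.42, 0.671 and 1.37; DNA was not analysed here, and whether such a difference arose in the clone, was present in part of the WT population or follows from CD38 loss stays untested.

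A second pattern was a set of genes at the floor in 1 group only: 15 genes at 5 CPM or more in WT lay under 0.15 CPM in every CD38 KO library, against 2 in the reverse direction, LY6E and SCAT1. Named after their values were seen, they included FGFR2, RAB32 and LINC02238, a non-coding RNA at 161.4 ± 1.45 CPM (SD, n = 3) in WT with 0 counts in every CD38 KO library, at least 3322-fold lower, beside CTSL, DDIT4L, PAXX, MGST1, ZNF536 and SPIN3. A deletion reaching the neighbouring genes is argued against for the 15 genes as a set, since their nearest neighbours had a median log2 fold change of -0.0847. This median cannot decide for single genes, as the neighbours ran from -1.496 (ZNF681) to 1.743 (CCR2). Neighbours with a mean under 1 CPM were left out. The test on low depth decides nothing, since the selection at 5 CPM fixed its outcome, at least 350.3 predicted counts per library at the floor. Libraries of another cell line could not be decided: 5 of 7097 genes at 20 CPM or more in WT (0.0705%) were at the floor, between the shares set for and against it. This share lay below the one set for another line. The outcome against it needed no such gene at all. CTSL and ZNF536 had already been seen at the floor, so that outcome could not occur. Loss of transcription of single genes may be a property of the clone, which the design confounds with the loss of CD38.

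Another pattern was the opposite movement of cell cycle genes by phase, tested on lists that left out the genes described above. Of 37 further G2 and M-phase genes 30 rose and 2 fell, with a median log2 fold change of 0.976 (camera adjusted p = 1.74e-11, adjusted p = 0.0204 with an estimated correlation). Of 31 further S-phase genes 23 fell and 3 rose, with a median of -0.416 (camera adjusted p = 3.23e-06, adjusted p = 0.0357 with an estimated correlation), which argues against more cells in cycle with the phases in the same proportion. A single knockout library is argued against, since the G2 and M-phase median was at least 0.951 with any of them left out. A larger share of cells in G2 and M phase may account for the pattern, and a change in the expression of these genes within each phase was not tested.

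Hypotheses on single regulators were also tested. SPI1 fell, yet of 25 tested PU.1-dependent innate genes 36% fell and 14 genes rose, with a median log2 fold change of 0.40 (camera adjusted p = 0.129), which argues against a joint fall of that program. FCGR2B and TLR6 were lower, at -3.66 and -2.31, while CLEC7A and ALOX5AP rose by 2.22 and 2.07 on the log2 scale. STAT3 and SOCS3 rose, and of 18 tested STAT3-response genes 9 rose and 4 fell, with a median of 0.170 (camera adjusted p = 0.129), which left a STAT3 response undecided.

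The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every split but the real one puts WT and CD38 KO libraries in both groups. The difference between WT and CD38 KO then enters the spread within groups. Low gene counts in those splits therefore do not measure false calls in the real one. With edgeR, 1 split, the real one, gave as many as 8934 changed genes, and the highest of the others gave 0 (155 to 347 at an unadjusted p under 0.05, against 10111). At 2-fold, 1 split gave 2266 genes and the highest other gave 0; other tools were not run on the splits. For the gene lists 1 split gave 10, and the highest other gave 4. For the chromosomes 5 of the splits, the real one included, gave 2, and the highest other also gave 2.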
